A study of Homo sapiens with 8 samples.

How the data were processed

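Small RNA was sequenced from scaffold-free cardiac organoids grown from a commercial human episomal induced pluripotent stem cell line. Per the labels' protocols, organoids received endothelin-1 (ET-1), a peptide that drives hypertrophic growth of cardiomyocytes, at 10 nM for 24 h from day 14 of culture, or no ET-1. Total RNA of 4 organoids was extracted per condition with a kit for small samples, and libraries were made with the QIAseq miRNA kit, which ligates adapters to small RNAs and can tag each molecule. Whether reads were collapsed by molecular tag, the mapper, the miRNA database and the genome build are not given in the sources used here. Groups were taken from the treatment label, which gives 3 control libraries (A, B and D) and 5 ET-1 libraries (A, B, C, D and F). No label says that the libraries came from separate differentiations or cultures, so p-values measure only the spread between these libraries, which may be technical.

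The main input was the deposited table of raw counts per mature miRNA, whole numbers for 2632 miRNAs. A companion table deposited by the authors as CPM holds a size-factor-scaled signal: each value is the raw count times 1 constant per library, and its columns sum to 886533 to 1039698. The scaling method of that table is not given in the sources used here. All 4839 of its values above 0 came within 0.01 of a whole number of reads after division by the smallest nonzero value of the library, and all 4839 equalled the deposited count. The count test on those recovered reads, added after the data were seen, called the same number of miRNAs, 55. The count table lists 1 miRNA more than the scaled table, with 0 counts.

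Library totals ranged from 165698 to 264278 counts, and 354 of the 1063 miRNAs with a count in any library had one in every library. At this depth precision is limited for miRNAs with few counts. No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom between libraries of 1 group was 11.3 to 71.0. Exact (Clopper-Pearson) 95% binomial intervals cover counting error only, since reads need not be independent molecules.

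The main test was edgeR's quasi-likelihood F-test with robust dispersion estimates, trimmed-mean (TMM) factors, the default expression filter with a minimum count of 10, and treatment as the sole term. An adjusted p (Benjamini-Hochberg) under 0.05 was a call. Fold changes are ET-1 against control with their standard error (SE), and levels are TMM-scaled CPM as mean ± SD. The filter kept 263 miRNAs with 99.6% of the counts. For 20 miRNA lists, camera was run with a preset correlation of 0.01 on the same counts, for lists with at least 3 tested members, and repeated with an estimated correlation and with fry, which asks whether a list's members move on balance in 1 direction and does not compare them with other miRNAs. For 7 library measures a two-sided exact permutation test over the 56 splits of 8 libraries into 3 and 5 was used, with Benjamini-Hochberg adjustment over the 7. The smallest p these splits can give is 0.0179.

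The design, the lists, the alternatives and the rule for named miRNAs were fixed before the data were examined. The rule names the 10 higher and 10 lower called miRNAs with the largest fold change, the 6 most abundant miRNAs, up to 3 abundant members and each called member of every tested list, and 6 miRNAs linked to hypertrophy or hypoxia whatever their values (miR-208a-3p, miR-208b-3p, miR-21-5p, miR-132-3p, miR-212-3p and miR-210-3p). Where under 5 miRNAs passed in a direction, those with the smallest p would have been added, which was not needed.

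Alternatives were DESeq2 size factors within edgeR, upper-quartile factors, total counts alone, other low-count filters, DESeq2's Wald test, limma-voom, limma on log2 of the deposited CPM with pseudocounts of 1 and 0.1, the replicate letter as a block, dispersion estimates that are not robust, counts summed over names with the same miRNA number and arm, an adjusted p of 0.1, and each library left out in turn. The sums joined members such as miR-30a-5p and miR-30c-5p whether or not they are near-identical. In that setting a named miRNA took the value of its sum. Added after the data were seen were scaling or testing on miRNAs with a miRBase number up to 1000, a correction for GC content, and the joint removal of control B and ET-1 F. The GC correction was a loess curve per library (span 0.75, prior count 2) of log2 CPM deviations on the GC content of the side of the hairpin that holds the arm, used as an offset. Hairpins were matched by name to GENCODE 29 (GRCh38), which gave a value for 256 of the 263 tested miRNAs. Coordinates come from that annotation lookup, are 1-based, and are not the authors'. Mature sequences shared by several hairpins, such as those of miR-129-5p, miR-133a-3p or miR-30c-5p, cannot be assigned to 1 locus. Near-identical members can share reads (miR-30b-5p with miR-30c-5p, miR-199a-3p with miR-199b-3p, miR-133a-3p with miR-133b, miR-365a-3p with miR-365b-3p, miR-17-5p with miR-106a-5p, and the miR-320 family), so their values are uncertain, and how the authors' counting treated such reads is not given in the sources used here.

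The procedure was tested on simulated data, drawn from the real means, library sizes and dispersions of 1063 miRNAs, with 200 changed in each of 5 simulations of the comparison of ET-1 with control. Of the changed miRNAs that passed the filter, 75 of 106 (70.8%) with a 2-fold change and 127 of 131 (96.9%) with a 4-fold change were called. False calls were 4.27% of all calls. The simulated miRNAs were drawn independently, and the groups differed only by the changes put in. This rate thus does not cover other differences between the groups, such as a trend with GC content. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.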

Results

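Mature miRNAs were counted in 3 libraries of untreated human cardiac organoids and 5 libraries of organoids exposed to 10 nM ET-1 for 24 h, with RNA of 4 organoids in each library. Totals were 264278, 179701 and 241083 counts in control A, B and D, and 212382, 165698, 228567, 196228 and 174430 in ET-1 A, B, C, D and F. The most abundant miRNAs were miR-122-5p, known as the main liver miRNA, with 150165 ± 16435 CPM in control (SD, n = 3) and 165656 ± 34983 in ET-1 (SD, n = 5), miR-1246 and miR-7704. In control A, miR-122-5p took 14.7% of the counts (Clopper-Pearson 95% interval 14.6 to 14.8%). The endothelial miR-126-3p, the muscle miR-1-3p and the pluripotency-associated miR-302a-3p were also abundant, with 29345 ± 8129, 26913 ± 7861 and 16438 ± 7463 CPM in control (SD, n = 3).

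The comparison of ET-1 with control asks which miRNAs respond to a hypertrophic stimulus. The largest change was in miR-129-5p, which rose 12.7-fold, from 227 ± 60.2 CPM (SD, n = 3) to 2863 ± 301 CPM (SD, n = 5), a log2 fold change of 3.66 ± 0.22 (SE; edgeR adjusted p = 8.9e-08). In GENCODE 29 (GRCh38) its sequence is carried by MIR129-1 on chromosome 7 at 128207872 to 128207943, intergenic on its strand, and by MIR129-2 on chromosome 11 at 43581394 to 43581483, in introns of 2 long non-coding RNAs. Also higher were miR-6126 (log2 fold change 2.06 ± 0.39, SE), miR-760 (1.98 ± 0.34), miR-10401-5p (1.84 ± 0.49), miR-92b-5p (1.76 ± 0.49), miR-885-3p (1.68 ± 0.37) and miR-204-3p (1.46 ± 0.34), with edgeR adjusted p of 0.0036, 0.0023, 0.021, 0.026, 0.0091 and 0.012. The ranges of the groups overlapped for miR-92b-5p. Counts per control library were low: 6 to 11 for miR-6126, 5 to 11 for miR-760, 5 to 17 for miR-10401-5p and 4 to 5 for miR-885-3p. Without control A the calls on miR-10401-5p, miR-92b-5p and miR-885-3p were lost (adjusted p = 0.092, 0.11 and 0.065), and without control D those on miR-92b-5p, miR-885-3p and miR-204-3p (0.084, 0.052 and 0.066). The lower miRNAs included miR-208a-5p, from an intron of the cardiac myosin gene MYH6 (chromosome 14, 23388596 to 23388666), and miR-194-5p, miR-30c-5p, miR-374a-5p and miR-145-5p. All but miR-194-5p fell by 1.70 ± 0.51, 1.39 ± 0.22, 1.39 ± 0.42 and 1.37 ± 0.28 on the log2 scale (SE), with edgeR adjusted p of 0.037, 0.0013, 0.034 and 0.0055, while miR-194-5p went from 117 ± 8.35 CPM (SD, n = 3) to 41.1 ± 12.4 (SD, n = 5; edgeR adjusted p = 0.0047). The ranges of the groups overlapped for miR-208a-5p and miR-374a-5p and were apart for the other 3. The call on miR-208a-5p was lost without control A, control B, ET-1 B or ET-1 D (adjusted p = 0.086, 0.14, 0.071 and 0.054), and without control B its log2 fold change was −1.04. That on miR-374a-5p was lost without ET-1 B (0.068). miR-365a-3p, miR-505-3p and miR-140-3p fell by 1.36 ± 0.45, 1.17 ± 0.37 and 1.15 ± 0.37 on the log2 scale (SE; edgeR adjusted p = 0.047, 0.041 and 0.042). Their counts per ET-1 library were low, at 1 to 8, 3 to 13 and 2 to 6. Without control A or control D all 3 of these calls were lost, as they were without ET-1 C, with adjusted p of 0.053 to 0.12. Those on miR-365a-3p and miR-140-3p were also lost without control B or ET-1 F, those on miR-505-3p and miR-140-3p without ET-1 B, and those on miR-365a-3p and miR-505-3p without ET-1 D, with adjusted p of up to 0.12. Among other settings, the libraries of letters A, B and D alone, without a block, ended all 3 calls (adjusted p = 0.12, 0.084 and 0.11) and the removal of both control B and ET-1 F those on miR-365a-3p and miR-140-3p (0.16 and 0.18). GC correction ended the calls on miR-365a-3p and miR-505-3p (adjusted p = 0.12 and 0.061), limma on the log2 of the deposited CPM with a pseudocount of 0.1 those on miR-365a-3p and miR-140-3p (0.066 and 0.055), and the absence of a low-count filter that on miR-140-3p (0.082).

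In all, 55 of 263 tested miRNAs changed, 32 higher and 23 lower, of which 16 and 14 changed over 2-fold. The 2 groups did not overlap for 63 miRNAs, where chance gives 3.57% of those tested. Calls on miR-129-5p, miR-6126, miR-760, miR-145-5p, miR-194-5p and miR-455-3p (which fell by 1.30 ± 0.29 on the log2 scale, SE) held under every alternative that tested them. Calls were short of the threshold in 15 of 27 alternatives for miR-21-5p and miR-365a-3p, 14 of 27 for miR-15b-5p, 12 of 25 for miR-140-3p, 10 of 27 for miR-320a-3p and miR-423-3p, 8 of 27 for miR-503-5p and miR-505-3p, 7 of 27 for miR-208a-5p, 6 of 27 for miR-25-5p and miR-92a-1-5p, 5 of 27 for miR-125b-5p and miR-133a-3p and 5 of 22 for miR-374a-5p. For the other 15 named calls this was so in 1 to 3 alternatives. The number of calls was 18 without control A, 27 without control D and 36 without ET-1 C, and 13 of the 39 without ET-1 B were lower. The balance of directions followed the scaling: upper-quartile factors gave 20 higher and 34 lower, and total counts alone 17 higher and 47 lower, because they shift the median log2 fold change of the tested miRNAs by −0.14 and −0.29.

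**Figure D1:**
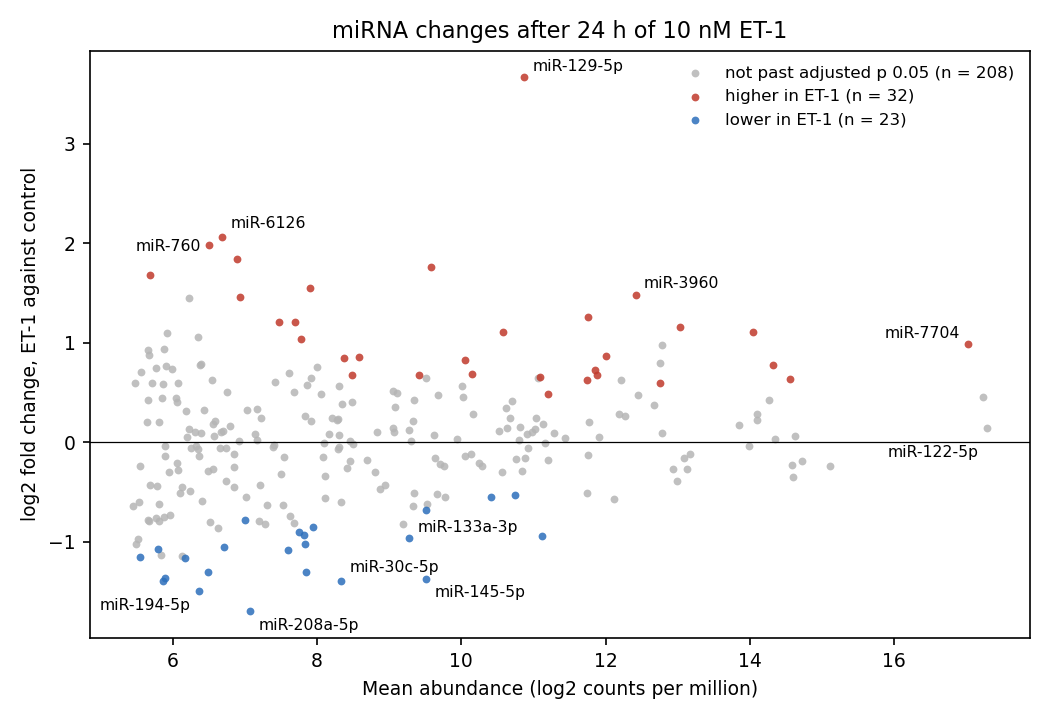
Each point is 1 of the 263 tested miRNAs, with its mean abundance in log2 CPM on the x axis and its log2 fold change in ET-1 against control on the y axis. The 32 higher (red) and 23 lower (blue) miRNAs differ in abundance: the lower ones lie at 11.1 log2 CPM or below, the higher ones extend to the abundant miR-7704, and miR-129-5p stands apart at 3.66.

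Many of the higher miRNAs have GC-rich hairpins and high numbers in the miRBase catalogue, which are given to later entries. Of the 32 higher miRNAs, 15 carry a number above 1000, against 0 of the 23 lower and 50 of the 263 tested. Among them were miR-3960 (2.80-fold, log2 fold change 1.48 ± 0.17, SE), miR-4466 (2.92-fold, 1.54 ± 0.23), miR-4492 (2.39-fold, 1.26 ± 0.19) and the abundant miR-7704 (1.97-fold, 0.98 ± 0.23), with edgeR adjusted p of 9.3e-05, 0.00078, 0.00078 and 0.011. MIR3960 lies in a coding exon of CDK9 (chromosome 9, 127785833 to 127785923) and MIR7704 in a coding exon of HOXD1 (chromosome 2, 176188843 to 176188901), while MIR4466 (chromosome 6, 156779678 to 156779731) and MIR4492 (chromosome 11, 118910708 to 118910787) are intergenic on their strands. These are annotated positions, and whether the counted reads came from these loci was not tested. The median GC content was 61.9% for the higher, 49.1% for the lower and 52.1% for all tested miRNAs. It was taken on the arm's side of the hairpin, not on the mature sequence, and over the whole hairpin for names without an arm. Those names include miR-3960, miR-4466, miR-4492 and miR-7704, so they were measured differently from the arm-named miRNAs. Each ET-1 library favoured GC-rich miRNAs more than each control library. A GC slope per library was fitted to each miRNA's deviation from its mean log2 CPM over all libraries. It was 0.086 ± 0.050 log2 CPM per 10 points of GC in ET-1 (SD, n = 5) and −0.144 ± 0.028 in control (SD, n = 3). Slopes of such deviations balance around 0 over the libraries. Only the difference between groups is thus informative, not the signs. The slope was chosen after the rise of fold change with GC was seen and restates it per library. With GC corrected, a setting added after the data were seen, 32 miRNAs were called, 16 higher and 16 lower, and miR-3960, miR-4466, miR-4492 and miR-7704 were no longer past the threshold (edgeR adjusted p = 0.14, 0.14, 0.061 and 0.28). The call on miR-7704 was also lost without control D (adjusted p = 0.073).

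**Figure D2:**
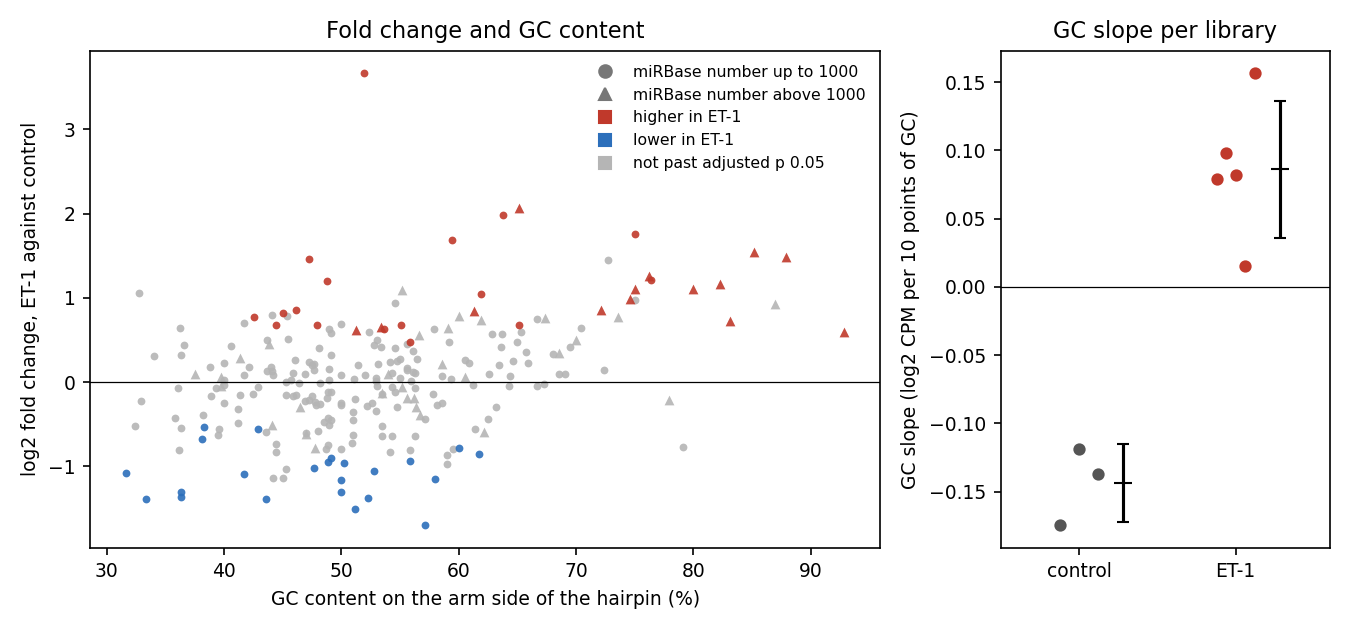
The left panel plots each miRNA's log2 fold change in ET-1 against control over GC content in percent, with triangles for miRBase numbers above 1000. GC content is that of the miRNA's side of the hairpin, or of the whole hairpin where the name gives no arm. The right panel gives the GC slope of each library in log2 CPM per 10 points of GC, with mean and SD bars. It was fitted to deviations from each miRNA's mean over all libraries, so only differences between libraries count, not signs. The 5 ET-1 libraries lie between 0.016 and 0.156 and the 3 control libraries between −0.175 and −0.119.

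Among the muscle miRNAs, 1 of 6 tested members fell, 0 rose and 5 did not pass the threshold. That member, miR-133a-3p, which is specific to heart and skeletal muscle, went from 877 ± 256 CPM (SD, n = 3) to 446 ± 146 (SD, n = 5), a fall by 0.96 ± 0.27 on the log2 scale (SE; edgeR adjusted p = 0.026). The call was lost without control A, control B or ET-1 B (adjusted p = 0.090, 0.089 and 0.058). Its hairpins are MIR133A1 on chromosome 18 (21825698 to 21825785) and MIR133A2 on chromosome 20 (62564912 to 62565013), both within exons of host non-coding RNAs. The more abundant miR-1-3p had a log2 fold change of −0.23 ± 0.23 and miR-208a-3p, the other arm of the MYH6 hairpin, −0.82 ± 0.31 (SE; edgeR adjusted p = 0.51 and 0.070), and miR-208b-3p −0.59 ± 0.36 (adjusted p = 0.27). The camera adjusted p of the list was 0.34, and 0.64 with an estimated correlation. Adjusted over the list alone, 1 member was higher and 2 lower. The higher one, miR-486-5p, a muscle miRNA that is also abundant in blood cells, had a log2 fold change of 0.57 ± 0.22 (SE; edgeR adjusted p = 0.073 over all tested miRNAs), with 173 ± 22.9 CPM in control (SD, n = 3) and 258 ± 41.8 in ET-1 (SD, n = 5). It falls outside the rule for named miRNAs and was chosen after its value was seen, and the lower ones were miR-133a-3p and miR-208a-3p. The share of counts in these miRNAs was 3.28% ± 0.90 in control (SD, n = 3) and 2.24% ± 0.47 in ET-1 (SD, n = 5; exact permutation p = 0.089, adjusted p = 0.25).

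**Figure D3:**
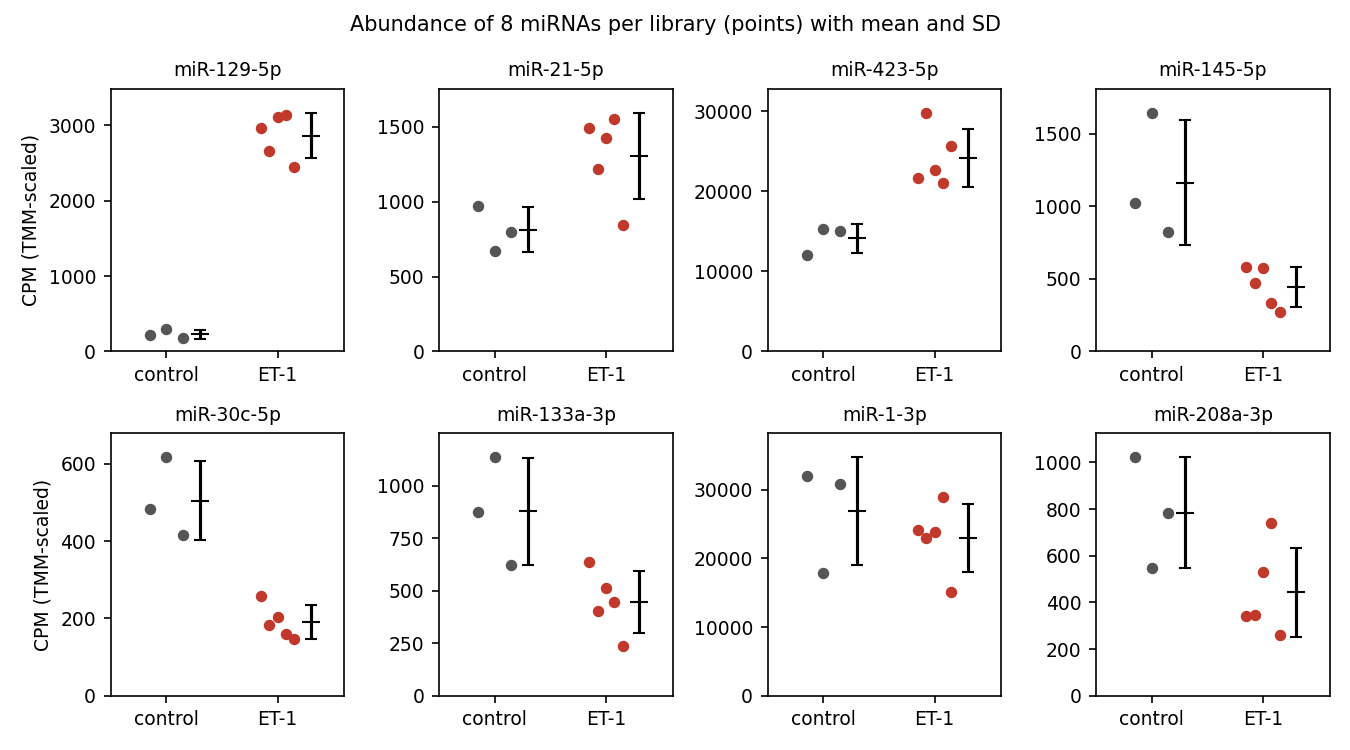
Points are libraries and bars are mean and SD of TMM-scaled CPM (linear axes from 0) for control (n = 3, grey) and ET-1 (n = 5, red). For miR-129-5p, miR-423-5p, miR-145-5p and miR-30c-5p the 2 groups do not overlap, while those of miR-21-5p, miR-133a-3p, miR-1-3p and miR-208a-3p do.

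Of the 13 tested miRNAs reported to oppose cardiomyocyte hypertrophy or to fall in it, 4 fell and 0 rose: miR-145-5p, miR-30c-5p, miR-30b-5p (by 1.30 ± 0.35 on the log2 scale, SE; edgeR adjusted p = 0.021) and miR-133a-3p. The abundant members miR-26a-5p and miR-30d-5p had log2 fold changes of −0.24 ± 0.19 and 0.03 ± 0.15 (SE). The call on miR-30b-5p was lost without control A (adjusted p = 0.12). Adjusted over the list alone, 0 were higher and 4 lower. The camera adjusted p was 0.098, and 0.56 with an estimated correlation, while fry gave 0.045. It passed camera without control B (adjusted p = 0.022), without control D (0.039), with a filter of 10 CPM in 3 libraries (0.0086, 17 members tested) and, a setting added after the data were seen, without control B and ET-1 F (0.034). Of 14 tested pro-hypertrophic miRNAs 1 rose and 1 fell. The riser was miR-21-5p, which increases in stressed myocardium, from 814 ± 153 CPM (SD, n = 3) to 1307 ± 287 (SD, n = 5), a log2 fold change of 0.68 ± 0.22 (SE; edgeR adjusted p = 0.043). It was past the threshold neither under upper-quartile factors (adjusted p = 0.13) nor without any 1 of control A, B or D or ET-1 A, B, C or D, with adjusted p of up to 0.20. The member that fell was miR-22-3p, by 0.93 ± 0.24 on the log2 scale (SE; adjusted p = 0.021, and 0.064 without control A). Adjusted over the list alone, 0 were higher and 1 lower, and the camera adjusted p was 0.50 (0.64 with an estimated correlation). miR-132-3p, induced by calcium signalling through CREB, had 0.74 ± 0.34 (SE; adjusted p = 0.13), and its cluster partner miR-212-3p, with 0 to 3 counts per library, was too low to test. All 4 tested calcium- and CREB-responsive miRNAs were short of the threshold, miR-23a-3p with −0.80 ± 0.28 (SE; adjusted p = 0.058), the camera adjusted p was 0.61 (0.72 with an estimated correlation), and 0 were higher and 2 lower adjusted over the list alone.

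Calls among stromal miRNAs went both ways. Of 5 tested fibroblast and fibrosis miRNAs, miR-145-5p and miR-199a-3p fell, miR-21-5p rose and 2 did not pass. miR-145-5p, a smooth muscle and pericyte miRNA from an intron of CARMN (chromosome 5, 149430646 to 149430733), went from 1162 ± 429 CPM (SD, n = 3) to 445 ± 139 (SD, n = 5). miR-199a-3p, processed in part from the DNM3OS transcript, fell by 1.02 ± 0.26 on the log2 scale (SE; edgeR adjusted p = 0.018, and 0.065 without control A or 0.056 without control D). For this list camera gave an adjusted p of 0.29 (0.56 with an estimated correlation, 0.045 with fry), and 1 was higher and 2 lower adjusted over the list alone. In the endothelial list 1 of 9 fell: miR-125b-5p, by 0.94 ± 0.27 on the log2 scale (SE; adjusted p = 0.026, and 0.075 without control A or 0.099 without control B). miR-126-3p, the endothelial marker, had −0.19 ± 0.21 (SE). The camera adjusted p was 0.42 (0.64 with an estimated correlation, 0.045 with fry), and 0 were higher and 1 lower adjusted over the list alone. Of the smooth muscle cluster 2 of 4 members were tested, too few for a list test.

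**Figure D4:**
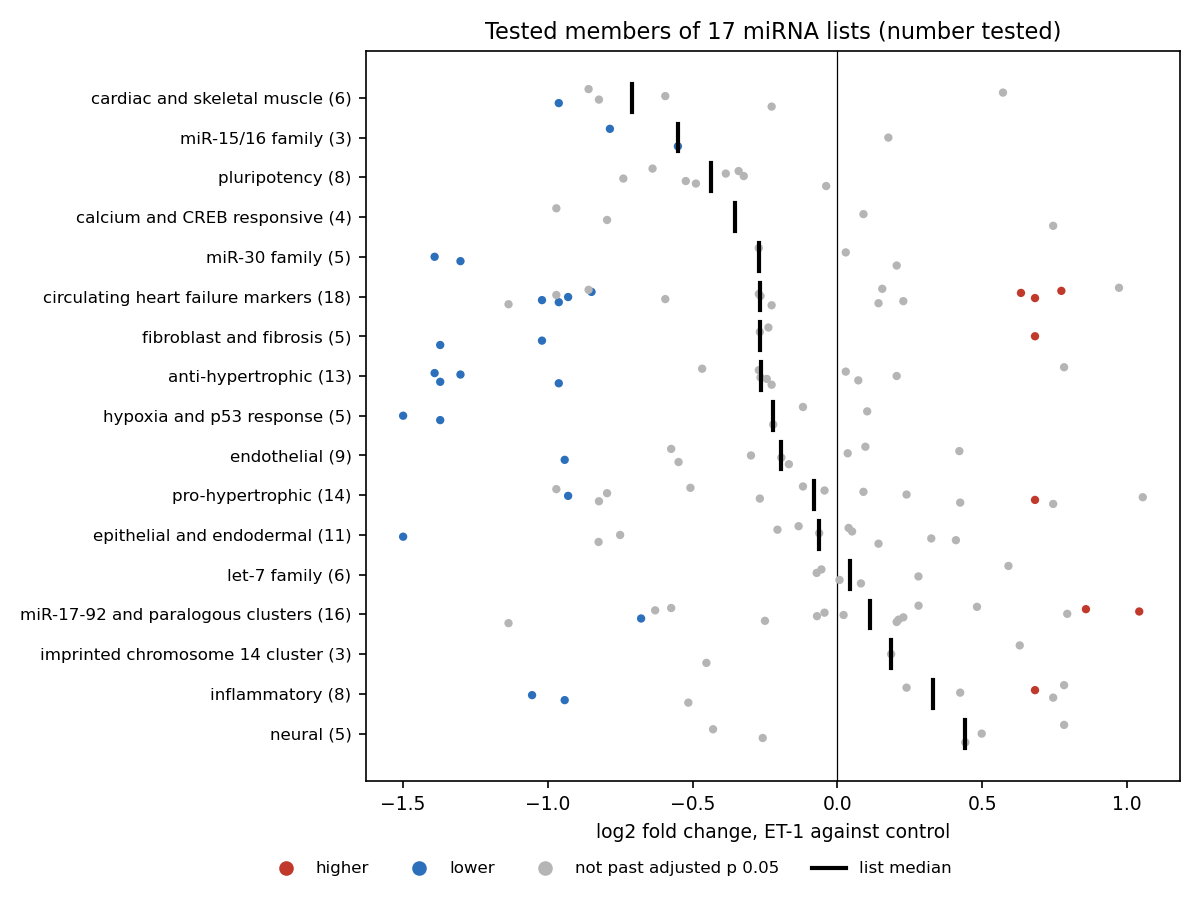
Each row is 1 of the 17 tested lists, each point a tested member at its log2 fold change in ET-1 against control (x axis), coloured where it passed the threshold, and the black bar is the list's median. The muscle list has the lowest median, −0.71, and the neural list the highest, 0.44, and called members lie on both sides of 0 in 5 lists.

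Among miRNA families, 2 of 5 miR-30 members fell (miR-30b-5p and miR-30c-5p), while summed family counts had a log2 fold change of −0.11 (edgeR adjusted p = 0.70), and miR-30d-5p, miR-30e-5p and miR-30a-5p, which hold most of them, had 0.03 ± 0.15, −0.27 ± 0.25 and 0.20 ± 0.24 (SE). Of 3 tested miR-15/16 members, miR-15b-5p and miR-503-5p fell, by 0.55 ± 0.18 and 0.79 ± 0.24 on the log2 scale (SE; adjusted p = 0.043 and 0.036). Both calls were lost without control A, control B, control D, ET-1 B or ET-1 C, and that on miR-15b-5p also without ET-1 D or ET-1 F, with adjusted p of up to 0.11. The hypoxia and p53 list had 2 of 5 lower, miR-194-5p and miR-145-5p, while the hypoxia-induced miR-210-3p had 0.10 ± 0.19 and the p53 target miR-34a-5p −0.12 ± 0.23 (SE). The camera adjusted p of the miR-30, miR-15/16 and hypoxia lists were 0.26, 0.34 and 0.22 (each 0.56 with an estimated correlation), fry gave 0.045, 0.013 and 0.013, and each had 0 higher and 2 lower adjusted over the list alone. The miR-17-92 and paralogous clusters went both ways, with 2 of 16 higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.90, and 0.94 with an estimated correlation): miR-25-5p and miR-92a-1-5p rose by 1.04 ± 0.28 and 0.86 ± 0.23, and miR-17-5p fell by 0.68 ± 0.17 on the log2 scale (SE; edgeR adjusted p = 0.022, 0.022 and 0.016). The calls on miR-25-5p and miR-92a-1-5p were lost without control A or control D, with adjusted p of up to 0.13, with total counts alone (0.071 and 0.090) and with the filter of 10 CPM (0.053 and 0.057). That on miR-25-5p was also lost with GC corrected (0.056) and with the libraries of letters A, B and D alone (0.084), that on hsa-miR-92a-1-5p with upper-quartile factors (0.051) and no low-count filter (0.0846), and that on miR-17-5p without control A (adjusted p = 0.065).

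Of 18 miRNAs described as circulating heart failure markers, 3 rose and 4 fell. The risers were miR-423-5p, a plasma marker of heart failure, from 14148 ± 1814 CPM (SD, n = 3) to 24173 ± 3607 (SD, n = 5), a log2 fold change of 0.77 ± 0.18 (SE; edgeR adjusted p = 0.011), miR-320a-3p with 0.63 ± 0.17 (SE; adjusted p = 0.021) and miR-21-5p. The 4 that fell were miR-133a-3p, miR-22-3p, miR-199a-3p and miR-423-3p, the last by 0.85 ± 0.27 on the log2 scale (SE; adjusted p = 0.043). Both miR-423 arms come from MIR423 in a UTR of NSRP1 (chromosome 17, 30117079 to 30117172). The call on miR-423-5p was lost without control A or control D (adjusted p = 0.065 and 0.053), that on miR-320a-3p without control A, control D or ET-1 C (0.10, 0.087 and 0.051), and that on miR-423-3p without any 1 of the libraries except ET-1 A and ET-1 C, with adjusted p of up to 0.15. The call on miR-320a-3p also missed the threshold with total counts alone (adjusted p = 0.17), as did that on miR-423-5p (0.071). For the list, camera gave an adjusted p of 0.34 (0.56 with an estimated correlation), and 4 were higher and 6 lower adjusted over the list alone.

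Lists of other cell types showed few calls. In the epithelial and endodermal list 1 of 11 fell, miR-194-5p (0 higher and 1 lower adjusted over the list alone), while miR-122-5p, miR-200c-3p and miR-375-3p had 0.14 ± 0.20, 0.05 ± 0.21 and 0.04 ± 0.18 (log2 fold change, SE). All 8 tested pluripotency miRNAs had negative fold changes with 0 past the threshold. Examples were miR-302a-3p with −0.04 ± 0.34 (0.14 with GC corrected) and miR-302d-3p with −0.39 ± 0.30 (SE). The estimated correlation among the members of this list was 0.71, so their shared sign cannot be read as 8 separate observations. In the neural list 0 of 5 passed, with miR-9-5p at 0.78 ± 0.55 and miR-7-5p at 0.50 ± 0.41 (SE). The let-7 family had 0 of 6 past the threshold, with let-7e-5p at 0.28 ± 0.19, and the imprinted chromosome 14 cluster 0 of 3, with miR-432-5p at 0.63 ± 0.30 (SE). These 4 lists also had 0 past the threshold adjusted over the list alone. The inflammatory list had 1 higher, miR-21-5p, and 2 lower of 8, miR-146b-5p (by 1.05 ± 0.27 on the log2 scale, SE; edgeR adjusted p = 0.021, and 0.090 without control A) and miR-125b-5p, with the same numbers adjusted over the list alone. The camera adjusted p were 0.42 for the epithelial, 0.29 for the pluripotency and 0.90 for each of the neural, let-7, imprinted and inflammatory lists (0.72, 0.72 and 0.94 with an estimated correlation). For the neural, inflammatory and miR-17-92 lists camera pointed lower although medians (0.44, 0.33 and 0.11) and means (0.21, 0.05 and 0.05) were positive; fry pointed higher for the neural and miR-17-92 lists and lower for the inflammatory list. Blood cell miRNAs and the chromosome 19 cluster had 0 and 2 tested members.

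In camera, 0 of the 17 lists passed an adjusted p of 0.05, with 3 at an unadjusted p under 0.05. With an estimated correlation 0 passed (0 unadjusted), and fry called 6 (8 unadjusted). Without control B the pluripotency and the hypoxia and p53 lists also passed camera, as lower (adjusted p = 0.022 and 0.024). They also did so without both control B and ET-1 F (0.034 each). These p-values rest on the preset correlation, and these fits were not repeated with an estimated one. With all libraries the estimate was 0.71 for the pluripotency list (camera adjusted p = 0.72 with it) and 0.012 for the hypoxia and p53 list. The pluripotency calls thus assume far less correlation than was estimated. None of the 7 library measures passed either, and with the smallest possible p at least 3 of them would have to reach it for any to pass. The first principal component, with 44.8% of the variance, separated the groups (exact permutation p = 0.0179, the smallest possible, adjusted p = 0.13). The number of miRNAs detected was 634 ± 34.3 in control (SD, n = 3) and 587 ± 25.8 in ET-1 (SD, n = 5; exact permutation p = 0.11, adjusted p = 0.25). With counts thinned to the smallest library it was 588 ± 5.51 and 562 ± 6.83 (exact permutation p = 0.0179, the smallest possible, adjusted p = 0.0625). Total counts averaged 228354 and 195461 (exact permutation p = 0.21, adjusted p = 0.35). The share of counts in the pluripotency list was 3.24% ± 1.31 (SD, n = 3) and 2.31% ± 0.78 (SD, n = 5; exact permutation p = 0.25, adjusted p = 0.35). The share in the most abundant miRNA ranged from 14.7% to 19.2% in control and from 15.5% to 20.5% in ET-1 (exact permutation p = 0.57), and the second principal component gave an exact permutation p of 0.68.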

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

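The tests on miR-129-5p and on muscle miRNAs, the GC slope per library and the GC correction were chosen after the results were seen. Among the 81 results checked for an ET-1 library far from the other 4, 1 stood out, where chance gives about 5%: miR-6126, with 238 CPM in ET-1 B against 137 in the next library and 98.2 in the lowest, a gap of 0.720 of the range (critical value 0.71). Its call held without ET-1 B.

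The 55 changed miRNAs were not matched by other splits of the libraries. Of the 56 splits into 3 and 5, 1 gave as many, the real one, and the highest of the others gave 2. A chance assignment of libraries is thus unlikely to give the count, though 1 in 56 is the strongest result these splits allow. The splits cannot tell ET-1 from any other difference between the groups. For the lists, the real split called 0 and the highest of the others 4; since each of the 56 splits gives at least 0, this comparison says nothing about chance.

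The first pattern is that the higher miRNAs were GC-rich and carried high miRBase numbers. A GC bias between libraries remains open and is a candidate explanation, because fold change also rose with GC among tested miRNAs numbered up to 1000 (Spearman rho 0.217, 95% interval 0.084 to 0.344, Pearson r 0.255, permutation p = 0.0016). GC content here is that of hairpin sequence, and that of the mature miRNAs was not measured. The 14 higher, high-numbered miRNAs with a GC value had a median log2 fold change of 1.04 (quartiles 0.76 to 1.23). With GC corrected it was 0.42 (0.27 to 0.65), with a median SE of 0.18 against 0.19 before. The fold was smaller for 12 of them and negative for 2, and 3 stayed past the threshold as higher while 1 passed it as lower. They were picked as higher in the same counts that the GC curve was fitted to. Some shrinkage was thus built in and does not by itself argue for a GC bias. The GC slope of the libraries follows the treatment, so the correction would also remove a response to ET-1 that follows GC content, which stays open and untested.

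The second pattern is the rise of miR-129-5p. A single library as its source is argued against, since the lowest log2 fold change with 1 library left out was 3.40. More neural cells, where this miRNA is abundant, are argued against only as a gain that raises the tested neural miRNAs as much as miR-129-5p. The highest upper 95% bound among these 5 was 2.13, that of miR-9-5p, below the lower bound of 3.12 for miR-129-5p. A gain diluted in miRNAs that other cells also make, or of cells with little of these 5, is not covered. Whether a whole hairpin rose cannot be told apart from a change in the 5p arm alone. For MIR129-2, its 3p arm miR-129-2-3p averaged only 2.88 counts per library, 5 in total in control and 18 in ET-1. For MIR129-1, which carries the same 5p sequence, the 3p arm was not examined. GC correction gave a log2 fold change of 3.74 for hsa-miR-129-5p, so its rise did not depend on the GC trend. A response of miR-129-5p to ET-1 is a hypothesis that stays open, since no test here separates it from other differences between the groups.

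The third pattern is the lower level of some muscle miRNAs. A lower share of cardiomyocytes predicts equal falls of miR-133a-3p and miR-1-3p, whose log2 ratio differed between groups by −0.79 (exact permutation p = 0.089, adjusted p = 0.089). The control libraries had −5.20 (A), −3.97 (B) and −5.62 (D) and the ET-1 libraries −6.01 to −5.24, so the difference rests largely on control B. A lower share therefore cannot be told apart from a change specific to miR-133a-3p, and a response to ET-1 stays open. Against an equal fall of all muscle miRNAs, miR-486-5p had a log2 fold change of 0.57 ± 0.22 (SE), but this is 1 member that blood cells also make, so it excludes nothing.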

How the results depend on the processing

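The alternatives that use miRNAs numbered up to 1000, GC correction, recovered reads or the joint removal of control B and ET-1 F were chosen after the data were seen. All 35 named called miRNAs kept their direction under each alternative that tested them, past the threshold in 775 of 931 values and short of it in 156, and the other 39 named passed it in 44 of 1048. All of the 55 calls with a value had the same sign under each other setting, while 2 of the 54 with a GC value changed sign with GC correction. The main 55 (32 higher, 23 lower) became 20 higher with upper-quartile factors, 17 higher and 47 lower with total counts, 39 lower with no low-count filter, 19 higher and 37 lower with 10 CPM in 3 libraries (which kept 444 miRNAs, more than the main filter), 20 higher and 35 lower with limma on log2(CPM + 1), 20 higher with log2(CPM + 0.1), 32 (16 higher) with GC correction, 30 (15 higher, 15 lower) on numbers up to 1000 alone, and 87 (40 lower) at an adjusted p of 0.1. The scaling, filter and CPM settings named here shifted the median log2 fold change by −0.14 to −0.29; the last follows from its threshold, GC correction shrank the folds of high-numbered miRNAs, and for numbers up to 1000 the cause was not tested beyond the fewer miRNAs tested. Without ET-1 C and F, unblocked, 27 were called (19 higher, 8 lower), with fewer libraries. With 1 library left out the count ranged from 18 (control A) to 57, 11 to 30 higher and 4 to 32 lower. Lists called were 6 with fry, 1 (anti-hypertrophic) with the 10 CPM filter, 3 (anti-hypertrophic, pluripotency, hypoxia and p53) without control B and ET-1 F, and 0 to 3 with 1 library left out; the cause was not tested. For the 7 library measures the adjusted p can hardly pass 0.05, so their alternatives say nothing about stability.

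With the replicate letter as a block, edgeR called 61 miRNAs with 8 libraries and 59 with letters A, B and D, and 0 lists. Each of these fits shared only 45 of the main 55 calls. The labels do not say that letters pair libraries, but the titles number the control and ET-1 libraries of letters A, B and D consecutively. Those numbers have gaps, among them where controls of letters C and F would stand in such an order. Whether further libraries were made is not given in the sources used here. The same-letter correlations of deviations were 0.04, 0.37 and 0.09 for A, B and D. With so few libraries they cannot decide the point, so pairing stays open. Not every library correlated best with its own letter: control A did so with ET-1 D (0.49). Depth limits miRNAs with few counts, which the filter left untested.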

Other observations

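The tests of arm ratios and the share of high-numbered miRNAs were chosen after the values were seen. For 33 hairpin names both arms were tested, and the log2 ratio of the 5p to the 3p arm was compared between groups for each. The exact permutation p adjusted over the 33 pairs was 0.0982 at the least, so 0 passed 0.05, with 9 at an unadjusted p under 0.05. The groups did not overlap for 10 of the pairs, where chance gives 3.57%. The largest differences, ET-1 minus control, were −1.95 for miR-30b and −1.87 for miR-204 (exact permutation p = 0.0179, adjusted p = 0.0982 for each). In 1 pair, miR-423, edgeR called both arms in opposite directions, though the miR-423-3p call was lost without any 1 of 6 libraries. The log2 ratio of miR-423 was 5.46 ± 0.30 in control (SD, n = 3) and 7.10 ± 0.50 in ET-1 (SD, n = 5), higher in 5 of 5 ET-1 libraries than in any control (exact permutation p = 0.0179, the smallest possible, adjusted p = 0.0982). Such ratios do not depend on the scaling factors.

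The share of counts in tested miRNAs numbered above 1000 was 32.4% ± 5.05 in control (SD, n = 3) and 41.5% ± 3.45 in ET-1 (SD, n = 5). Abundant members weigh heavily in it, so it need not reflect these miRNAs as a class. Mean levels in control and ET-1 were 82730 and 163379 CPM for miR-7704. For miR-1246, which was not called (edgeR adjusted p = 0.13), they were 124418 and 170423 CPM.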
